A study of Naumovozyma castellii with 24 samples.

How the data were processed

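The measured quantity was the number of RNA-seq reads per gene in 24 libraries of Naumovozyma castellii, and the values used were the raw counts that the authors deposited. Per the submitters' processing notes, reads were aligned with TopHat2 and counted with HTSeq 0.6.0. The TopHat2 version, the genome build, the annotation and the strand setting of the counting were not given in the sources used here. Per the labels, the 18 libraries of the deletion experiment were stranded single-end libraries with reads of 42 bp, and the 6 libraries of the oxygen experiment were stranded paired-end libraries with reads of 90 bp made by another sequencing provider. Per the labels, RNA was extracted with 1 of 2 kits, and which kit served which sample was not stated. The 2 experiments were therefore fitted apart and their levels were not compared by a test.

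The deposited counts of the deletion experiment had 5852 entries, 1 per exon, which were summed to 5648 genes, and those of the oxygen experiment had 5648 entries, 1 per gene. The 5 counter entries of each file, such as reads outside genes, were kept only as measures of library quality. Each label gave a group and a replicate number, and all 24 libraries were used. Gene symbols and neighbours came from the annotation table of assembly ASM23734v1, which held 5589 of the genes, 4484 of them with a symbol. No coordinates are given. Reads that matched several places were left out of the counts and came to 17.27 to 42.84 per 100 gene counts in the deletion experiment. Levels of near-identical genes are therefore uncertain, which applies to NCAS0B01030, NCAS0B02500 and NCAS0C00720, and to the neighbours NCAS0A10130 and NCAS0A10140.

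Libraries were scaled by TMM, and genes were kept by filterByExpr with its minimum of 10 counts, which left 5544 genes in the deletion experiment and 5559 in the oxygen experiment. Each of 17 comparisons was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, default settings, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The deletion experiment was fitted with all 18 libraries and 1 mean for each of 8 groups, which shared the estimate of the spread, since 6 of the 8 groups had 2 libraries. The oxygen experiment was fitted with its 6 libraries. The square root of the common dispersion was 0.199 in the deletion experiment and 0.068 in the oxygen experiment. Adjusted p-values of genes came from edgeR and those of gene lists from limma. An SE of a log2 fold change was its absolute value divided by the square root of F. Levels are counts scaled to library size with TMM (CPM), as mean ± SD over libraries. Interactions compared 2 log2 fold changes and were tested in the same fit.

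The 27 gene lists were written by S. cerevisiae gene name from textbook knowledge. They were regulators, haem synthesis, hypoxic genes of S. cerevisiae, anaerobic cell wall and sterol uptake, ergosterol synthesis, fatty acid synthesis and desaturation, respiratory chain and ATP synthase, TCA cycle, glycolysis and fermentation, hexose transport, gluconeogenesis and glyoxylate, iron uptake and use, and zinc and other metal transport. The others were sulfur assimilation and methionine, oxidative stress defence, heat shock and general stress, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrial ribosomal proteins, proteasome, amino acid synthesis, phosphate supply, cell wall, cell cycle and DNA replication, mating, meiosis and sporulation, and quiescence and stationary phase. Lists with 3 or more tested members were tested with camera in limma 3.58.1 with its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. Fry tests whether the genes of a set move on balance one way and does not compare them with other genes.

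The genes named were chosen by a rule. In the 5 main comparisons, which were hypoxia, CoCl2 in WT and the 3 deletions without CoCl2, it took the 6 largest rises and the 6 largest falls. Genes had to have an adjusted p under 0.05, a mean log2 CPM of 4 or more, and every library of one group above every library of the other. It added 3 members of each of up to 6 lists with a list adjusted p under 0.05, and up to 8 called members of the regulators and hypoxic genes. In the other comparisons it took 3 genes per direction, without the condition on every library for interactions of 4 groups. Genes named beyond this rule are further list members or other called genes. The locus deleted as ROX2 is not named by a symbol in the annotation table. NCAS0E02010 was picked from the counts after they had been seen, and it is described without being equated with ROX2.

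For the hypoxia comparison, the replicate numbers were checked for pairing by correlating the deviations from the group mean of libraries with the same number. The 3 correlations across genes were 0.152, 0.307 and 0.137, all above the threshold of 0.1, so the numbers were taken to pair the libraries. A fit with the replicate number as a block called 741 genes (302 higher, 439 lower), beside 361 without it. The hypoxia values in the results come from the fit without the block unless the block is named. Floors and ratios of counts used the same TMM-scaled library sizes as the levels.

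The tests, the filter, the scaling, the lists, the naming rule and most alternatives were chosen before the data were examined. Those alternatives were median-of-ratios size factors, total counts without a scaling factor, minimum counts of 1 and 50, DESeq2 1.42.0, the replicate number as a block, only the libraries of the compared groups, leaving out each library in turn, and the list tests above. Alternatives added after the data had been seen were offsets that removed a smooth trend on coding length in each library (lowess span 0.3), fits without rox1 replicate 1 and rox2 replicate 3, the CoCl2 libraries alone with a block, hypoxic gene sets without a minimum fold, list tests of hypoxia with a block and an estimated correlation together, and robust estimation of the spread. The default instead of the robust setting of edgeR was settled after counts from a robust fit had been seen. A fit that leaves 1 library in a group takes that library to vary like the other groups.

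The fits were tested on simulated data with the depth and the pooled spread of each experiment. Groups of the deletion experiment varied unequally, with a median gene SD from 0.071 log2 in rox1/rox2 to 0.249 in rox2 with CoCl2. The simulated shares therefore do not cover the effect of unequal spread. Of genes simulated with a 2-fold change, 100% were recovered in the hypoxia comparison, 71% for CoCl2 in WT, and 65%, 76% and 66.3% for rox1, rox2 and rox1/rox2 against WT without CoCl2. False calls made up 7.8% of the calls in the hypoxia simulation and 2.9% to 5.2% in the others. The simulations of rox1, rox2 and rox1/rox2 had 164, 192 and 172 calls, against 3, 4 and 6 in the data. With fewer calls the adjustment is stricter, so the shares for the deletion strains overstate the recovery expected in the data. Correlations between comparisons that share WT libraries were set beside 50 simulations of unchanged groups against the same controls. The coding lengths used for the length correction came from the same annotation table, and 97.6% of them were multiples of 3.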

Results

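Naumovozyma castellii is a relative of S. cerevisiae, in which Rox1 represses hypoxic genes while oxygen is present. The data comprised 2 RNA-seq experiments on this yeast. In the deletion experiment, WT cells and strains lacking ROX1, ROX2 or both were grown to an A600 of 1 and then kept for 2 h without or with 0.6 mM CoCl2, a salt used to mimic low oxygen. WT and rox2 had 3 libraries each without CoCl2 and the 6 other groups had 2, with 5.59 M to 12.74 M gene counts per library. In the oxygen experiment, WT cells grew for 6 h in 21% or 1% oxygen, with 3 libraries each and 11.99 M to 12.18 M gene counts. The comparisons asked which genes changed in low oxygen, with CoCl2 and without the ROX genes. They also asked whether the CoCl2 response depended on the ROX genes, and whether losing both differed from the sum of losing each.

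ROX1 stood at 19.2 ± 0.926 CPM in WT and 20.2 ± 0.811 in rox2. It had 1 count over both rox1 libraries against 622 in WT, which was 363-fold lower (95% interval 64.9 to 14400). No ROX1 count was found in the 3 other groups without the gene, which put ROX1 at least 87.7-fold lower in rox1/rox2, at least 237-fold lower in rox1 with CoCl2 and at least 199-fold lower in rox1/rox2 with CoCl2. These intervals and floors of 3 counts cover counting error only. In WT, ROX1 rose with CoCl2 to 33.8 ± 1.76 CPM (log2 fold change 0.82, SE 0.194, adjusted p = 0.00552), and it stood at 28.9 ± 6.31 in rox2 with CoCl2. In the oxygen experiment it stood at 46.7 ± 8.44 CPM in normoxia and 38.3 ± 4.37 in hypoxia.

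No gene carried the symbol ROX2. NCAS0E02010 was the only one of 29 genes without counts in all 9 libraries of strains lacking ROX2 that had counts, 18 or more, in each of the 9 other libraries. It was picked after the counts had been seen. It stood at 1.79 ± 0.204 CPM in WT and 3.68 ± 1.27 in rox1, and was at least 14.9-fold lower in rox2 and at least 8.18-fold lower in rox1/rox2. With CoCl2, NCAS0E02010 rose to 15.3 ± 0.137 CPM in WT (log2 fold change 3.09, SE 0.34, adjusted p = 0.000124) but stood at 3.48 ± 1.49 in rox1, and this difference in response passed the test (−3.16, SE 0.52, adjusted p = 0.0203). No alternative fit is given for this call. NCAS0E02010 was at least 90.7-fold lower in rox2 and at least 89.4-fold lower in rox1/rox2 with CoCl2. In normoxia and hypoxia it stood at 10 ± 0.598 and 10.6 ± 0.549 CPM.

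**Figure D1:**
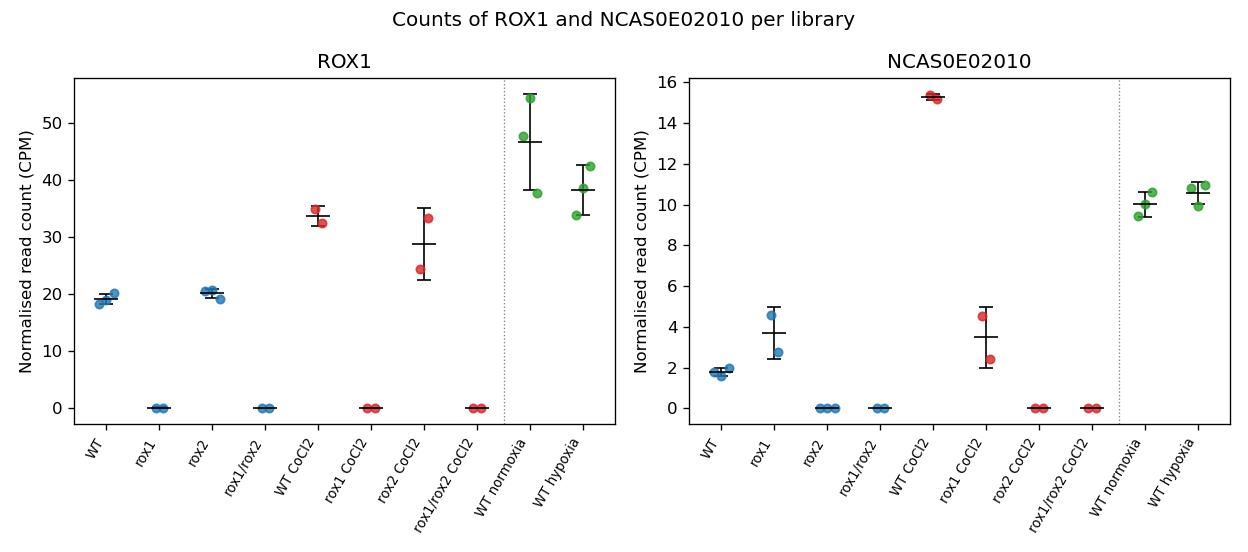
Scaled counts (CPM, vertical axis) of ROX1 and NCAS0E02010 in each library of the 10 groups, with mean and SD as bars. Blue points had no CoCl2, red points had CoCl2 and green points are the oxygen experiment: ROX1 stood at 19.2 CPM in WT and 0.0637 in rox1, and NCAS0E02010 at 15.3 CPM in WT with CoCl2.

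In 1% oxygen, HMX1, which encodes haem oxygenase, fell to 0.0594 of its level in 21% oxygen (log2 fold change −4.07, SE 0.207, adjusted p = 3.97e-06, n = 3 per group). AHP1, CTT1 and TRR2, which encode a peroxiredoxin, a catalase and a thioredoxin reductase, fell to 0.302, 0.4 and 0.409 (SE of log2 0.073, 0.066 and 0.05). CYC1, which encodes cytochrome c, fell to 0.368 (SE 0.099). YAP7 fell to 0.286 (SE 0.088), and the unnamed genes NCAS0H01340, NCAS0A09820, NCAS0I01310 and NCAS0F00650 fell to 0.153, 0.238, 0.257 and 0.319. INO1, which encodes inositol phosphate synthase, rose 2.46-fold (log2 1.30, SE 0.112, adjusted p = 0.000149). ANB1, which encodes the translation factor eIF5A of hypoxic cells, rose 2-fold (log2 1.00, SE 0.057, adjusted p = 7.15e-06). NCAS0C00240, NCAS0B00350, NCAS0F00110 and NCAS0D02180 rose 2.26-, 2.2-, 2.19- and 1.82-fold. Further members of the fixed lists that fell were the copper transporter genes CTR3 and CTR1 (log2 −2.30 and −1.52, SE 0.226 each) and the iron-sulfur scaffold gene ISU1 (−1.47, SE 0.122). In all, 147 genes rose and 214 fell among 5559 tested, of which 5 rose and 20 fell at least 2-fold. With the replicate number as a block, 302 rose and 439 fell. The number called without the block was 169 without normoxia replicate 1 and 193, 194 and 235 without hypoxia replicates 1, 2 and 3.

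Of 24 ergosterol synthesis genes, 19 fell and none rose in hypoxia (22 fell when adjusted over the list alone), with a median log2 fold change of −0.43 (camera adjusted p = 2.52e-39). Among them ERG5, ERG28 and ERG11 fell to 0.511, 0.514 and 0.607 (SE of log2 0.071, 0.103 and 0.046). Of 26 oxidative stress genes, 14 fell (14 over the list alone; median −0.24, adjusted p = 1.43e-40), and of 35 respiratory chain and ATP synthase genes, 17 fell (22 fell and 1 rose over the list alone; median −0.36, adjusted p = 7.52e-18), including COX12 at 0.567. These were the only list calls of hypoxia that held with an estimated correlation (adjusted p = 0.0172, 0.00287 and 0.00682), and with the block as well each reached 0.0857. Of 70 mitochondrial ribosomal protein genes, 13 fell (40 over the list alone; median −0.20, adjusted p = 4.25e-13, or 0.0661 with an estimated correlation), including RSM18 at 0.582. Amino acid synthesis had 9 of 60 genes fall (15 over the list alone; median −0.12, adjusted p = 1.82e-05, or 0.108 with an estimated correlation), including HOM3 at 0.751 and ARO3 at 0.757. The proteasome had 2 of 35 genes fall (12 over the list alone; median −0.14, adjusted p = 7e-05, or 0.0885 with an estimated correlation). Ribosome biogenesis had 7 of 106 genes rise (7 over the list alone; median 0.07, adjusted p = 0.000245, or 0.532 with an estimated correlation). Of 35 cell cycle genes, 4 rose, CLN1 and CLN2 among them (log2 0.34 and 0.37; list adjusted p = 0.0202, or 0.149 with an estimated correlation). Iron uptake and use had 2 of 17 genes rise and 2 fall (4 and 4 over the list alone), with a median of −0.02 and a mean of −0.31 (adjusted p = 0.0438, or 0.182 with an estimated correlation). That list call was also lost with the replicate number as a block (0.0786), with total counts (0.0507) and with the length correction (0.0522). The calls of NDE1 at 0.537, MRPL27 at 0.71 and LYS21 at 0.761 were lost without some single libraries. Those of MRPL37 at 0.692 and PUP3 at 0.87 were lost without any 1 library except normoxia replicate 2. RPN13 at 0.872 lost its call without any 1 library and with the length correction (adjusted p = 0.128). PUP3 and RPN13 were the only called proteasome genes. NDE1 reached 0.134, MRPL37 0.128, MRPL27 0.0647 and PUP3 0.12 without normoxia replicate 1, LYS21 0.0675 and RPN13 0.116 without hypoxia replicate 2, and RSM18 0.0518 without hypoxia replicate 3.

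Of 22 hypoxic genes of S. cerevisiae, 6 rose and 3 fell in hypoxia (9 and 4 over the list alone), with a median of 0.15 and a mean of −0.04, while the list test pointed up (adjusted p = 0.129). Besides ANB1, HEM13 for haem synthesis rose 1.57-fold (SE of log2 0.055), AUS1 for sterol import 1.46-fold (SE 0.065), the mannoprotein gene TIR3 1.4-fold (SE 0.084), and the regulator gene SUT1 1.38-fold (SE 0.08). COX5B and ERG11 fell to 0.733 and 0.607. The 5 anaerobic cell wall and sterol uptake genes had 2 rise (3 over the list alone; median 0.20, adjusted p = 0.000834, or 0.149 with an estimated correlation). Of 14 regulators 2 rose (median 0.05, mean −0.02, test up), of 8 haem genes 2 rose (median −0.04, mean 0.05, test up), and of 12 fatty acid genes 4 rose and 2 fell. Heat shock had 2 of 27 genes rise and 5 fall (5 and 10 over the list alone), with HSC82 at log2 −0.43 and HSP10 at −0.41. Of 31 cell wall genes 3 rose and 1 fell, and of 15 zinc and other metal transport genes 1 rose and 2 fell (median 0.01, mean −0.18, test down). Single genes rose in glycolysis (19 genes; median −0.02, mean 0.035, test up), gluconeogenesis (16 genes; median −0.04, mean −0.01, test up) and quiescence (15 genes), and single genes fell in the TCA cycle (15), sulfur assimilation (24) and meiosis (37). No member passed in hexose transport (7), cytosolic ribosomal proteins (109), phosphate supply (12) or mating (25), and none of the lists from regulators on passed the list test. With the replicate number as a block, 11 hypoxic genes of S. cerevisiae rose and 5 fell, 34 mitochondrial and 11 cytosolic ribosomal protein genes fell, and 19 amino acid and 10 proteasome genes fell. Ribosome biogenesis then had 11 genes rise, iron uptake 4 rise and 5 fall, heat shock 5 rise and 9 fall, regulators 2 rise and 2 fall, and cell wall 5 rise and 2 fall. The block also gave 6 fatty acid genes that rose and 2 that fell, 3 anaerobic cell wall and 3 quiescence genes that rose, and 2 gluconeogenesis genes in each direction. Glycolysis then had 2 rise and 1 fall, zinc and other metals 1 rise and 3 fall, sulfur assimilation 2 fall, and the respiratory chain 1 rise and 20 fall.

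With CoCl2, HMX1 rose 55.2-fold in WT (log2 fold change 5.79, SE 0.419, adjusted p = 6.1e-07, n = 2 against 3). YHB1, which encodes a flavohaemoglobin that removes nitric oxide, rose 61.1-fold (5.93, SE 0.361), HSP26, which encodes a small heat shock protein, 43.8-fold (5.45, SE 0.727), and EGO4 46.7-fold (5.55, SE 0.57). The near-identical genes NCAS0B01030, NCAS0B02500 and NCAS0C00720 rose 82.7-, 79.4- and 53.1-fold, but their levels were uncertain because shared reads were left out. NDE1, which encodes an external NADH dehydrogenase, rose 25.3-fold, the cytochrome c gene CYC7 11.1-fold (SE of log2 0.36), and HAP4, which activates respiratory genes in S. cerevisiae, 6.47-fold (SE 0.553). ANB1 fell to 0.249 (SE of log2 0.327, adjusted p = 0.000279). NCAS0H01220, NCAS0A10130, NCAS0A10140 and NCAS0E03170 fell to 0.168, 0.174, 0.193 and 0.197, of which the middle pair was uncertain for the same reason, and LGE1 fell to 0.208. Of 5544 genes tested, 1533 rose and 1074 fell, 822 and 429 of them at least 2-fold. With total counts 1872 rose and 623 fell, and the median fold change of all genes shifted by 0.244 log2. Without WT CoCl2 replicate 1 the number called was 1470. Reads outside genes were 7.9% and 7.89% of both WT CoCl2 libraries and at most 5.19% of the WT libraries.

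All but 1 of 24 ergosterol synthesis genes rose in WT with CoCl2 (23 also over the list alone; median 1.69, adjusted p = 3.67e-20, or 0.0173 with an estimated correlation), with ERG5 at 7.01-fold, ERG28 at 6.78-fold, ERG29 at 4.88-fold and ERG11 at 3.35-fold. Of 35 respiratory genes 33 rose (34 over the list alone; median 1.86, adjusted p = 3.62e-22, or 0.242 with an estimated correlation), among them COX12 at 9.09-fold, COX7 at 8.93-fold and SDH4 at 7.61-fold. The TCA cycle had 13 of 15 genes rise (median 1.45, adjusted p = 5.82e-05, or 0.421 with an estimated correlation), with LSC1 at 9.79-fold and LSC2 at 9.73-fold. Quiescence genes rose in 13 of 15 cases (median 1.41, adjusted p = 8.91e-05, or 0.34 with an estimated correlation), among them YGP1 at 16.8-fold and FMP16 at 14-fold. Of 109 cytosolic ribosomal protein genes 89 fell (97 over the list alone; median −1.23, adjusted p = 1.63e-16, or 0.514 with an estimated correlation), with RPL43B at 0.201, RPS28A at 0.21 and RPP2A at 0.221. Log2 fold changes with CoCl2 in WT also rose with coding length (rank correlation 0.14 across genes). After the length correction RPL43B went from −2.31 to −2.02 log2, RPS28A from −2.25 to −1.87 and RPP2A from −2.18 to −1.92. All of these stayed called. Ribosome biogenesis had 21 of 106 genes fall and 1 rise (3 and 1 over the list alone; adjusted p = 3.32e-07, or 0.592 with an estimated correlation), where DBP1 rose 3.99-fold and RPA14 at 0.316 and NOP6 at 0.321 lost their calls without WT CoCl2 replicate 1 (0.128 and 0.138). Cell cycle had 16 of 35 genes fall and 2 rise (adjusted p = 0.00018, or 0.34 with an estimated correlation), and cell wall 11 of 31 fall and 1 rise (0.00489, or 0.514 with an estimated correlation). Meiosis had 18 of 37 genes rise and 1 fall (adjusted p = 0.00489, or 0.457 with an estimated correlation), and gluconeogenesis 9 of 17 rise and 1 fall (0.00502, or 0.421 with an estimated correlation). Of 27 heat shock genes 16 rose and 5 fell (adjusted p = 0.00502, or 0.573 with an estimated correlation), with HSP104 at log2 3.49 and SSA2 at −0.90. Hypoxic genes of S. cerevisiae split into 10 that rose and 5 that fell (adjusted p = 0.283). Of these, CYC7 rose 11.1-fold, NCE102 8.05-fold and COX5B 4.02-fold, while ANB1 fell to 0.249 and AAC3, TIR3 and SUT1 fell as well (log2 −1.36, −0.95 and −0.89). Of 14 regulators 7 rose and 3 fell, with HAP4 at 6.47-fold and ECM22 at 2.6-fold, and UPC2 and IXR1 lower (log2 −1.09 and −1.07). Glycolysis and iron genes each had 3 rise and 3 fall, and for glycolysis the median of −0.11 and the mean of 0.20 differed in sign.

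**Figure D2:**
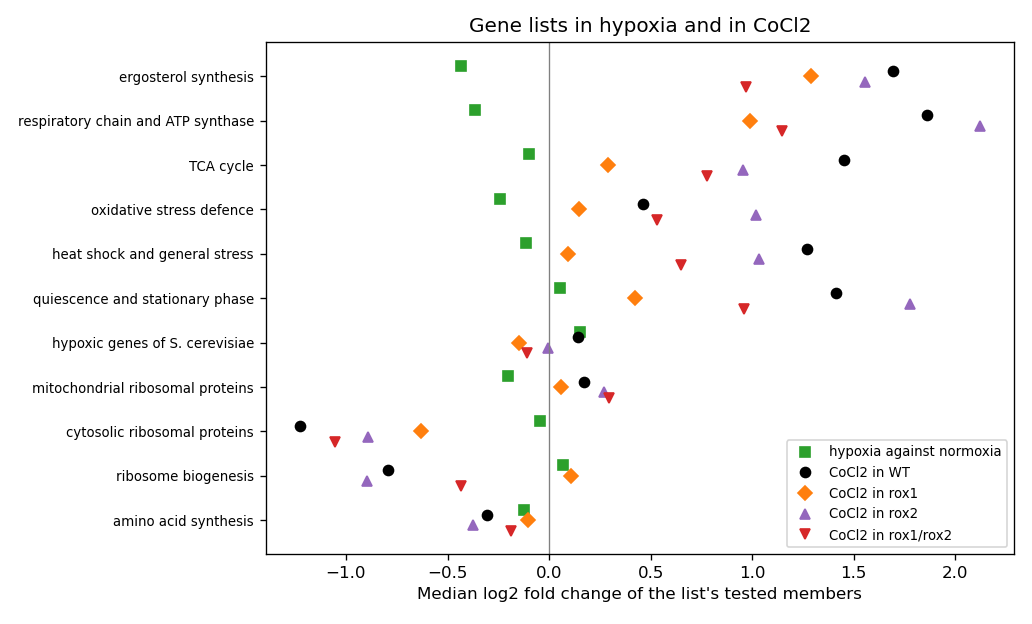
Median log2 fold change (horizontal axis) of the tested members of 11 gene lists in hypoxia (squares) and with CoCl2 in WT (circles), rox1 (diamonds), rox2 (upward triangles) and rox1/rox2 (downward triangles). Ergosterol synthesis stood at −0.43 in hypoxia and at 1.69 with CoCl2 in WT.

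HMX1, ERG5, ERG11, COX12, NDE1 and COX5B fell in hypoxia and rose with CoCl2, while ANB1, TIR3 and SUT1 rose in hypoxia and fell with CoCl2. AUS1 and HEM13 rose in both (log2 0.55 and 0.65 in hypoxia, 1.06 and 0.89 with CoCl2). Among the genes called in both, 105 were lower in hypoxia and higher with CoCl2 (59.1 expected from independent calls), 62 were higher in both (40.6 expected), 23 were lower in both (41.6 expected), and 32 were higher in hypoxia and lower with CoCl2 (28.6 expected). Across 5525 genes, which are not independent replicates, the log2 fold changes in hypoxia and with CoCl2 in WT had r = −0.137. The 20 genes at least 2-fold lower in hypoxia had 11 members rise and 1 fall with CoCl2 in WT (median 0.87, adjusted p = 0.00546, or 0.235 with an estimated correlation). In rox2 14 rose and 1 fell (median 1.15, adjusted p = 1.64e-06, or 0.118 with an estimated correlation), and in rox1/rox2 8 rose (median 0.90, adjusted p = 5.55e-10, or 0.0466 with an estimated correlation). The 5 genes at least 2-fold higher in hypoxia passed no list test, with 1 that rose and 2 that fell in WT.

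Without CoCl2, MSS11, which regulates adhesion and filamentous growth in S. cerevisiae, was higher in all 3 deletion strains, at 61.2 ± 4.43 CPM in rox1, 57.9 ± 5.03 in rox2 and 45.8 ± 1.35 in rox1/rox2 against 14.3 ± 3 in WT (n = 2, 3, 2 and 3). The rises were 4.27-, 4.04- and 3.2-fold (SE of log2 0.167, 0.156 and 0.169; adjusted p = 1.51e-05, 2.07e-05 and 0.000282), all against the same WT libraries. The untreated WT of this experiment had the lowest MSS11 level of all 10 groups, and MSS11 stood at 57.1 ± 3.14 CPM in the normoxic WT of the oxygen experiment. These rises, and the MSS11 interactions given further on, therefore rest on the 3 untreated WT libraries and cannot be assigned to the deletions alone. In rox1 the genes called were ROX1, MSS11 and the autophagy gene ATG41, which rose 4.1-fold from 41.3 to 169 CPM (log2 2.04, SE 0.293, adjusted p = 0.0126). ATG41 reached adjusted p of 0.126, 0.109 and 0.0633 without WT replicates 1, 2 and 3 and 0.256 without rox1 replicate 1. The number called in rox1 was 291 without rox1 replicate 2. In rox2 the genes called were MSS11, NCAS0E02010, CAR2 for arginine breakdown and ALD6 for acetaldehyde oxidation, and the latter pair fell to 0.383 and 0.465 (SE 0.223 and 0.173, adjusted p = 0.0383 each). Both reached 0.272 without rox2 replicate 2, and also lost their calls without each WT library or rox2 replicate 1. The number called in rox2 was 1 without each WT library and without rox2 replicate 2, 2 without rox2 replicate 1 and 23 without rox2 replicate 3. Reads outside genes were 14.47% in rox2 replicate 3, against at most 5.19% in WT.

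In rox1/rox2, NCAS0A11110, the neighbour of ROX1, rose 11-fold from 3.74 to 41.3 CPM (log2 3.46, SE 0.39, adjusted p = 0.00077), and NCAS0C04890 rose 4.48-fold (SE 0.369, adjusted p = 0.0382). NCAS0A00140 fell to 0.401 (SE 0.212, adjusted p = 0.025), and NCAS0G01490 fell by 2.14 log2 (SE 0.297, adjusted p = 0.00625). With MSS11 and ROX1 these were all 6 genes called, 3 higher and 3 lower, or 5 higher and 1 lower with total counts, where the median of all genes shifted by 0.268 log2. Without rox1/rox2 replicate 1 or 2 the number called was 3, and NCAS0C04890 and NCAS0A00140 lost their calls without any 1 library of either group (up to 0.39 without replicate 1 and 0.515 without replicate 2). The 2 rox1/rox2 libraries tested alone with WT gave 2796 calls, and the median gene SD was 0.071 log2 in rox1/rox2 and 0.078 in WT, against up to 0.249 in the other groups.

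Several gene lists passed the list test in the deletions, but none held with an estimated correlation. In rox1 the medians of the iron and proteasome lists were −0.15 each (adjusted p = 0.0221 each, or 0.999 with an estimated correlation), with 3 iron genes lower over the list alone. In rox2 the respiratory and cytosolic ribosomal protein lists had medians of 0.35 and 0.36 (adjusted p = 1.49e-09 and 1.05e-08, or 0.723 and 0.832 with an estimated correlation), with 7 respiratory genes higher over the list alone. The rox2 medians of the mitochondrial ribosomal, proteasome and cell cycle lists were 0.11, −0.15 and 0.17 (adjusted p = 0.0173, 0.000132 and 0.0286, or 0.832, 0.825 and 0.723 with an estimated correlation). In rox1/rox2 ribosome biogenesis had a median of −0.75 (adjusted p = 2.81e-18), heat shock 0.60 (1.58e-09; 11 of 27 higher over the list alone), TCA cycle 0.59 (5.41e-05; 8 of 15 over the list alone), respiratory chain 0.48 (1.93e-06) and ergosterol synthesis 0.20 (0.00251; 7 of 24 over the list alone), each 0.5 with an estimated correlation. Cytosolic ribosomal protein genes had a median of −0.39 in rox1/rox2 (adjusted p = 8.92e-07, or 0.631 with an estimated correlation). Amino acid, cell wall and iron genes had medians of −0.24, −0.26 and −0.28 there, and the regulators and hypoxic genes, which include ROX1 itself, −0.07 and −0.095, all 0.5 with an estimated correlation. The mitochondrial ribosomal and proteasome lists had medians of 0.165 each (0.591 with an estimated correlation).

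HSC82, which encodes HSP90, stood at 3096 ± 30.1 CPM in rox1/rox2 against 784 ± 115 in rox2 (log2 1.98, SE 0.295, adjusted p = 0.0032), and the genes of its partners AHA1 and STI1 rose by 2.12 and 1.71 log2 (SE 0.25 and 0.224, adjusted p = 8e-04 and 0.00189). HEM13 rose by 0.99 (SE 0.207, adjusted p = 0.0272), NCAS0A11110 rose 17-fold (log2 4.09, SE 0.424, adjusted p = 0.000406), and NCAS0G03920 rose by 2.82 (SE 0.566). TMA10, STP4 and ARG3, whose product makes citrulline for arginine, fell (log2 −5.31, −4.68 and −2.82). NCAS0C00720 also fell (−5.31), with the doubt on shared reads. In all 70 genes were higher and 54 lower, or 342 and 49 with total counts, with a shift of 0.29 log2. The number called was 37 and 68 without rox2 replicates 1 and 2, and 19 and 15 without rox1/rox2 replicates 1 and 2. The calls of NCAS0G03920, TMA10, STP4 and NCAS0C00720 were lost without either rox1/rox2 library (up to 0.244, 0.343, 0.311 and 0.396). Against rox1, 9 genes were higher and 9 lower in rox1/rox2 (17 and 6 with total counts, with a shift of 0.299). They included NCAS0A11110 (4.96-fold), CAR1 and SSP2 (log2 1.81 and 1.42), ARG3, MAE1 and NCAS0A02080 (−2.53, −2.26 and −2.16). Without rox1 replicate 1 or either rox1/rox2 library, edgeR called none of these (range of adjusted p up to 0.36), and without rox1 replicate 2 it called 506. With all libraries, 1148 genes had an unadjusted p under 0.05 and DESeq2 called 356.

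Losing both genes differed from the sum of the single losses for 22 genes, 8 above and 14 below that sum. The arginine breakdown genes CAR1 and CAR2 were above it (log2 3.17 and 2.58, SE 0.424 and 0.352, adjusted p = 0.00399 each), with CAR1 at 301 CPM in WT, 118 in rox2 and 493 in rox1/rox2. ARG3 was below it (−4.12, SE 0.46, adjusted p = 0.00103), at 51.1, 126, 153 and 21.6 CPM in WT, rox1, rox2 and rox1/rox2, as were ARG8 and ARG56 (−2.43 and −2.97). AHA1 and STI1 were above the sum (2.17 and 1.95, SE 0.36 and 0.324, adjusted p = 0.0129 each), and MSS11 was below it (−2.43, SE 0.24, adjusted p = 0.000443). NCAS0A04610 and NCAS0C05370 were also below it (−3.60 and −3.54, SE 0.56 and 0.587). Total counts gave 9 above and 10 below, with a shift of 0.322. The number called was 8, 14 and 12 without WT replicates 1, 2 and 3, 7 and 220 without rox1 replicates 1 and 2, 14, 13 and 60 without rox2 replicates 1, 2 and 3, and 8 and 5 without rox1/rox2 replicates 1 and 2. AHA1 reached 0.093, NCAS0A04610 0.0997 and NCAS0C05370 0.144 without rox1/rox2 replicate 2.

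**Figure D3:**
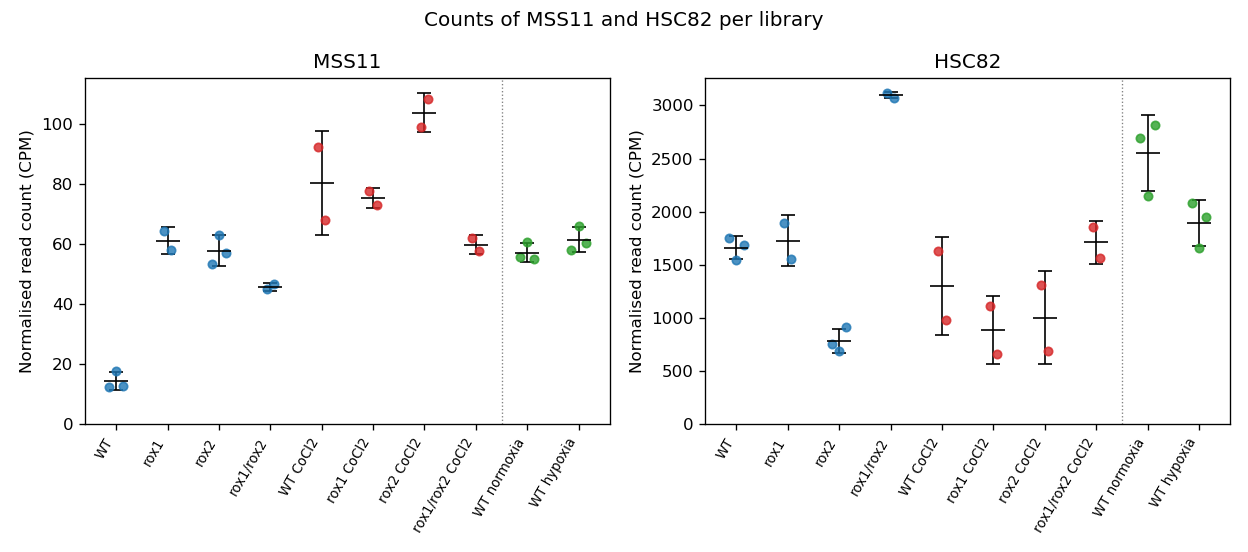
Scaled counts (CPM, vertical axis) of MSS11 and HSC82 in each library of the 10 groups, with mean and SD as bars and blue, red and green for libraries without CoCl2, with CoCl2 and of the oxygen experiment. MSS11 stood at 14.3 CPM in WT and 61.2 in rox1, and HSC82 at 784 CPM in rox2 and 3096 in rox1/rox2.

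HMX1 and the ergosterol genes rose with CoCl2 in every strain. HMX1 rose 22.8-fold in rox1, 130-fold in rox2 and 48.2-fold in rox1/rox2 (log2 4.51, 7.02 and 5.59, SE 0.518, 0.466 and 0.562, n = 2 against 2, 3 and 2). YHB1 rose 18.7-fold in rox1 and 19.1-fold in rox1/rox2, and IDP2 rose 81.9-fold in rox2 and 13.2-fold in rox1/rox2. LEU1 rose 10.9-fold in rox1 and HSP26 rose 56.5-fold in rox2. ARG3 fell to 0.174 in rox1 and 0.136 in rox2, NCAS0H01220 to 0.213 in rox1 and 0.243 in rox1/rox2, and ADE57 and HIS7 to 0.0871 and 0.101 in rox2. Ergosterol genes rose in 19, 22 and 16 of 24 cases in rox1, rox2 and rox1/rox2 (medians 1.29, 1.56 and 0.97), the only list whose calls in all 3 strains held with an estimated correlation (adjusted p = 0.00973, 0.021 and 0.0309). Respiratory genes rose in 14, 33 and 18 of 35 cases (0.279, 0.111 and 0.165 with an estimated correlation). Of 109 cytosolic ribosomal protein genes, 1, 54 and 1 fell, with medians of −0.63, −0.89 and −1.06 (0.745, 0.566 and 0.406 with an estimated correlation). The CoCl2 responses had rank correlations with coding length of 0.076, −0.2 and 0.029 in rox1, rox2 and rox1/rox2, against 0.14 in WT. The counts were 269 higher and 178 lower in rox1, 1458 and 1209 in rox2, and 243 and 78 in rox1/rox2. Total counts gave 295 and 67, 1794 and 701, and 233 and 48, with shifts of 0.172, 0.234 and 0.141. In rox1 the number called was 126 and 930 without rox1 replicates 1 and 2 and 201 without rox1 CoCl2 replicate 1. It was 1493 in rox2 without rox2 CoCl2 replicate 1, and in rox1/rox2 it was 40 and 46 without rox1/rox2 replicates 1 and 2 and 91 without rox1/rox2 CoCl2 replicate 1. In rox1, NCAS0F03100 fell to 0.172 but reached 0.0961 without rox1 CoCl2 replicate 1. In rox1/rox2, NCAS0H01880 and NCAS0F00120 fell to 0.212 and 0.283 but reached 0.138 and 0.233, and IDP2 reached 0.0939, without rox1/rox2 replicate 1.

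The CoCl2 response differed between rox1 and WT for 261 genes, 45 with a higher and 216 with a lower log2 fold change in rox1. NCAS0B02500, which rose from 4.83 to 379 CPM in WT, went from 3.71 to 6.01 in rox1 (difference −5.64, SE 0.871, adjusted p = 0.00883). Its level was uncertain because shared reads were left out. Reads that matched several places came to 42.84 and 37.72 per 100 gene counts in rox1 with CoCl2, against 24.43 and 23.76 in WT with CoCl2. The hexokinase gene HXK1 rose from 11.2 to 253 CPM in WT and went from 10.2 to 8.18 in rox1 (−4.85, SE 0.953, adjusted p = 0.0203). GPP2, which encodes a glycerol phosphatase, went from 2987 to 759 CPM in WT and from 2680 to 2808 in rox1 (2.04, SE 0.393, adjusted p = 0.0198). HSP104, GPH1 and TSL1 differed by −3.41, −2.87 and −2.09, NDE1 and QCR7 by −3.57 and −2.03, and ERG5, ERG4, ERG24 and ERG27 by −1.42, −1.30, −0.955 and −0.95. Members with a lower response numbered 4 of 24 for ergosterol synthesis, 6 of 35 for the respiratory chain (19 over the list alone) and 7 of 27 for heat shock (15 over the list alone), and all 10 list calls were lost with an estimated correlation (adjusted p of 0.468 to 0.667). The number called was 26, 24 and 90 without WT replicates 1, 2 and 3, 28 and 504 without rox1 replicates 1 and 2 (the latter 248 higher and 256 lower), 66 without WT CoCl2 replicate 1, and 431 and 19 without rox1 CoCl2 replicates 1 and 2. HXK1 and GPP2 reached 0.134 and 0.0997 without rox1 CoCl2 replicate 2. With total counts 85 genes were called (11 higher, 74 lower), and without rox1 replicate 1 and rox2 replicate 3 the number was 45 (10 higher, 35 lower).

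For rox1/rox2 the response differed from WT for 22 genes, 3 higher and 19 lower, with ISF1, NCAS0H01880 and HSP104 at −3.99, −3.98 and −3.06, and RIM2 and SMB1 at 1.43 and 1.20 (SE 0.237 and 0.21). For rox2 it differed for 5 genes, with YHI9, AVO2, SBH1 and RFA3 higher (1.06, 1.73, 1.24 and 1.14, SE 0.174, 0.27, 0.202 and 0.18) and MSS11 lower (−1.65, SE 0.236), at adjusted p = 0.0317 each. The rox2 calls fell to none without WT replicate 1 or 3, rox2 replicate 1 or 2, WT CoCl2 replicate 1 or rox2 CoCl2 replicate 2, to 1 without WT replicate 2 or WT CoCl2 replicate 2, and reached 164 without rox2 replicate 3, while 773 genes had an unadjusted p under 0.05 in edgeR and DESeq2 called 146. The rox1/rox2 calls numbered 8 and 5 without WT replicates 1 and 2, 4 and 5 without rox1/rox2 replicates 1 and 2, 34 and 5 without WT CoCl2 replicates 1 and 2, and 188 and 5 without rox1/rox2 CoCl2 replicates 1 and 2. ISF1, NCAS0H01880, RIM2 and SMB1 reached 0.147, 0.193, 0.126 and 0.166 without rox1/rox2 CoCl2 replicate 2, and AVO2, SBH1 and RFA3 0.222 each without WT CoCl2 replicate 2. MSS11 reached 0.101 without WT CoCl2 replicate 1. The rox2 differences followed coding length across genes, which are not independent replicates (rank correlation −0.639), and none was called after the length correction, where SBH1 dropped from 1.24 to 0.336 (adjusted p = 0.873) and RFA3 from 1.14 to 0.477 (0.827). AVO2 and MSS11 kept their differences after it, at 1.73 and −1.52 (adjusted p = 0.0526 each).

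On 1213 genes picked for a change of at least 2-fold in rox2, 789 risen and 424 fallen, 97.9% moved the same way in WT, 80.8% in rox1 and 96.3% in rox1/rox2. Their median log2 fold changes were 1.58 and −1.09 in WT, 0.50 and −0.43 in rox1, and 0.83 and −0.57 in rox1/rox2. Scaled to the WT response, the response was 0.375 in rox1 and 0.558 in rox1/rox2. Fold changes start from the untreated level of each strain. On the main axis of variation among the libraries (first principal component, 56.1%), untreated WT lay at −30, −30.4 and −24. Untreated rox1 lay at −30.6 and −25.3, and untreated rox1/rox2 at −9.1 and −7.7. With CoCl2, WT reached 53.5 and 30.8, rox1 4.6 and −14.9, and rox1/rox2 42 and 17.1. The smaller factor in rox1/rox2 thus goes with a shifted untreated level. Across all genes, which are not independent replicates, the CoCl2 responses correlated at r = 0.604 between WT and rox1, 0.867 between WT and rox2, and 0.835 between WT and rox1/rox2.

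**Figure D4:**
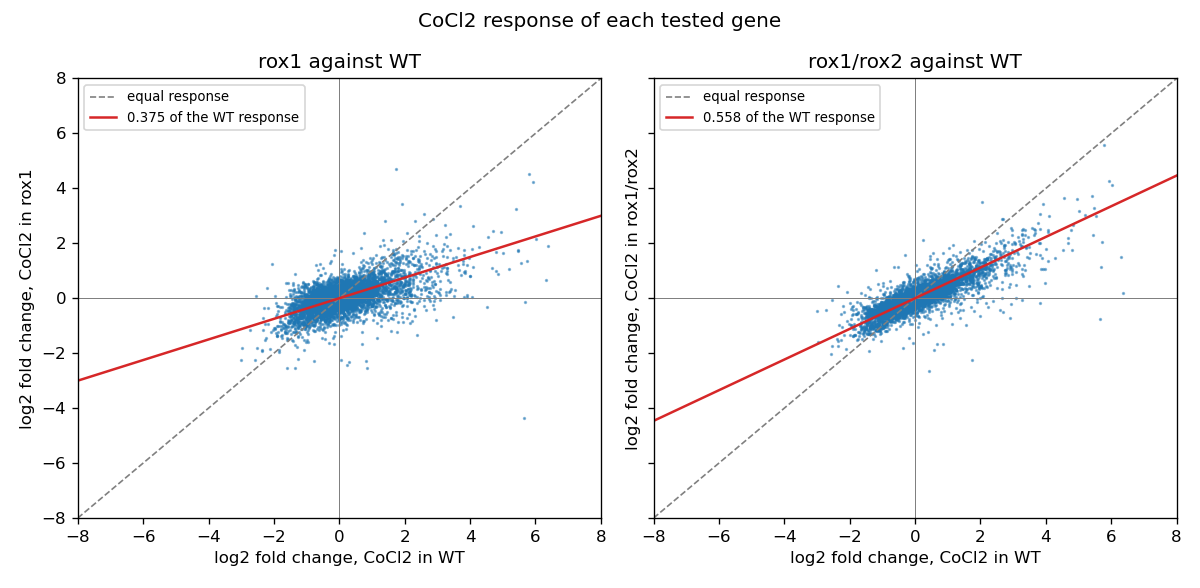
Log2 fold change with CoCl2 in rox1 and in rox1/rox2 (vertical axes) against that in WT (horizontal axes), 1 point per gene, with a line of equal response and a line for the fitted factor. The factor was 0.375 in rox1 and 0.558 in rox1/rox2.

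Compared with WT directly in CoCl2, rox1 had 258 genes higher and 716 lower, rox2 149 and 49, and rox1/rox2 69 and 209. The length correction left 3 calls for rox2. In rox1, NCAS0B02500, HXK1 and NCAS0B01030 were lower by −5.99, −4.95 and −4.86 log2 (SE 0.658, 0.758 and 1.002), and 25 of 35 respiratory and 12 of 24 ergosterol genes fell (0.416 each with an estimated correlation). The levels of NCAS0B02500 and NCAS0B01030 carried the doubt on shared reads. NCAS0G01840, NCAS0G04260 and NCAS0F03520 were higher by 2.63, 2.16 and 2.07, but lost their calls without rox1 CoCl2 replicate 2 (0.0722, 0.179 and 0.0765). In rox1/rox2, NCAS0A11110 was 2.39 log2 higher (SE 0.404), NCAS0G01840 2.31 (SE 0.508) and LSO1, an iron-responsive gene, 1.74 (SE 0.301), reaching 0.0577, 0.0933 and 0.0649 without rox1/rox2 CoCl2 replicate 2. NCAS0B01030, NCAS0C00720 and NCAS0B02500 were lower there by −7.88, −6.79 and −5.64 (SE 1.186, 1.325 and 0.647), with the doubt on shared reads, and NCAS0C00720 reached 0.115 without rox1/rox2 CoCl2 replicate 2. With total counts rox2 had 89 genes higher and 14 lower and rox1/rox2 had 85 and 85 with a shift of 0.167, and the shift in rox1 was −0.102. The number called was 276 without WT CoCl2 replicate 1 and 94 without rox1 CoCl2 replicate 2 for rox1, 10 without either WT CoCl2 library and 90 without rox2 CoCl2 replicate 2 for rox2, and 59 without WT CoCl2 replicate 2 and 51 without rox1/rox2 CoCl2 replicate 2 for rox1/rox2. With only the compared groups in the fit, edgeR called 98 genes for rox1, 4 for rox1/rox2 and none for rox2, where the full fit had 1266 genes with an unadjusted p under 0.05 and DESeq2 called 582. The CoCl2 libraries alone, with the replicate number as a block, gave 1380, 294 and 36 calls for rox1, rox2 and rox1/rox2. In every strain CoCl2 replicate 1 lay further from the untreated libraries than replicate 2. The counts without a block may therefore carry a replicate effect shared by the strains.

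In rox2 with CoCl2, genes with short coding sequences were higher than in WT, and the length correction took the 198 calls to 3 (1 higher, 2 lower). TMA7, which encodes a small ribosome-associated protein, was higher by 2.31 log2 (SE 0.352, adjusted p = 0.00706), as were NCAS0G02180 and NCAS0B08460 (2.68 and 2.31, SE 0.639 and 0.574), while NCAS0B04270, FLC3 and NCAS0H03600 were lower (−1.05, −0.93 and −0.905, SE 0.246, 0.195 and 0.17). Of the 198 genes called, 107 were among the shortest 10% of genes, up to 510 bp, and all of these were higher. The rank correlation of log2 fold change with coding length was −0.741 across genes, which are not independent replicates. Reads outside genes were 19.88% and 10.13% of both rox2 CoCl2 libraries. After the length correction none of these 6 genes was called, with TMA7 at 1.12 (SE 0.257, adjusted p = 0.192), NCAS0G02180 at 0.949 (0.729), NCAS0B08460 at 1.82 (0.269), NCAS0B04270 at −0.82 (0.292), FLC3 at −0.61 (0.292) and NCAS0H03600 at −0.74 (0.192). TMA7, NCAS0G02180, NCAS0B08460, NCAS0B04270, FLC3 and NCAS0H03600 also lost their calls without WT CoCl2 replicate 1, at 0.0877, 0.17, 0.188, 0.159, 0.0888 and 0.0982.

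**Figure D5:**
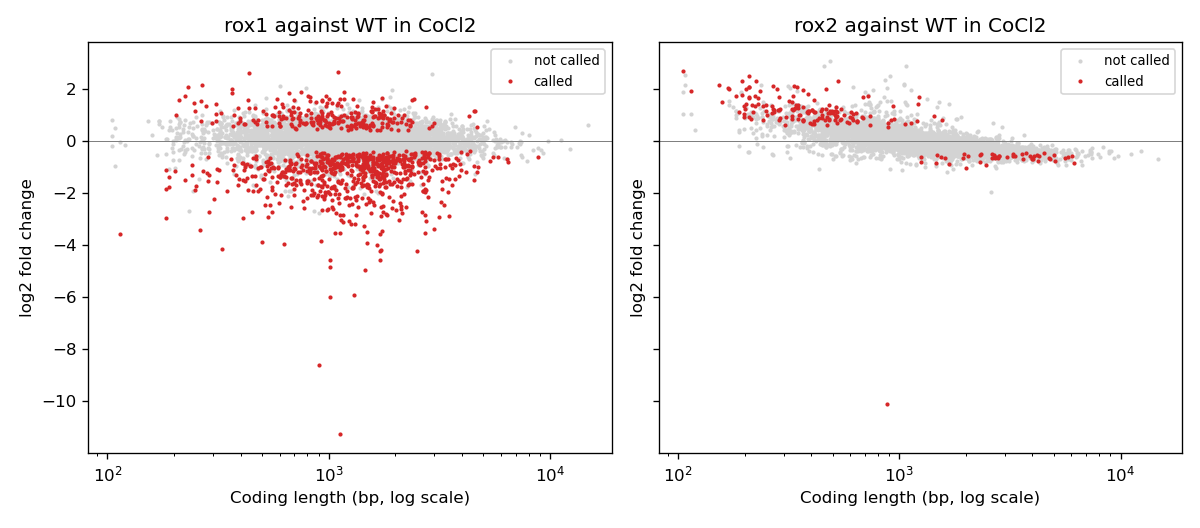
Log2 fold change (vertical axes) against coding length in bp (horizontal axes) for rox1 and rox2 against WT in CoCl2, 1 point per gene, with called genes in red. In rox2, 107 of the 198 called genes were at most 510 bp long.

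The responses to losing ROX1 or ROX2 were compared across 5544 genes, which are not independent replicates, against the same WT libraries. The log2 fold changes of rox1 and rox2 had r = 0.053 and a covariance of 0.00647, and unchanged groups simulated against the same controls had 0.436 and 0.0329. For rox1 and rox1/rox2 r was 0.264 against 0.385 in the simulation (covariance 0.0459 against 0.0332), and for rox2 and rox1/rox2 0.09 against 0.425 (0.0155 against 0.0327). The pair of rox1 and rox1/rox2 includes the deleted ROX1 itself, at −8.17 and −10.46 log2. With genes of mean log2 CPM 4 or more, which leaves out ROX1 at 3.79, its r was 0.14. The higher covariance of that pair can therefore not be assigned to other genes. The response to CoCl2 in WT and the effect of losing both genes had r = 0.47 against 0.382 simulated and a covariance of 0.232 against 0.0332, with 3 genes higher in both where 0.83 were expected from independent calls. MSS11, whose rise rests on the untreated WT libraries, was among them. Both comparisons use those libraries, so their calls are not independent. For rox2 and CoCl2 r was 0.317 against 0.438 (covariance 0.111 against 0.0334), and for rox1 and CoCl2 0.118 against 0.39 (0.0416 against 0.0332). The 3 WT libraries could not be split into 2 sets of 2 or more, so part of any excess may come from the shared controls. The simulations used the pooled spread, while WT libraries varied less (median gene SD 0.078 log2), so the simulated values were too high and an observed value below them says nothing about the deletions. For losing both genes and CoCl2 in WT, the covariance of 0.232 exceeded even the overstated 0.0332. This argues against spread among the shared WT libraries as the source of that excess. A state common to all 3 WT libraries was not simulated and stays possible.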

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

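The comparison of coding lengths, the uniform scaling of the CoCl2 response and the splits of libraries were specified after first results had been seen, and the short-gene pattern and several fold changes in rox1 were known by then. The test on NCAS0A11110 and its condition on leaving out libraries were set after its values had been seen.

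The CoCl2 response was weaker in rox1, with 261 genes whose response differed between rox1 and WT. A uniformly weaker response in rox1 would leave at most 5 such genes after the WT response was multiplied by the factor 0.375, and gene-specific differences would leave at least 20. The test gave 15 calls, only 3 of them among the 261, with 13 above and 2 below the scaled response. Such genes were ELO1 (1.99, SE 0.284, adjusted p = 0.0252) and LEU2 (2.09, SE 0.383) above and ARG3 (−2.02, SE 0.372) below it. At an unadjusted p under 0.05 there were 1373 genes before scaling and 737 after it. Each factor was fitted to the same fold changes that were then tested, which favours the scaling. By the condition set, a uniform scaling and gene-specific differences cannot be told apart in rox1. In rox1/rox2, scaling by 0.558 took the 22 calls of edgeR to 0, with a smallest adjusted p of 0.139 and 224 genes at an unadjusted p under 0.05. A trend of gene length between libraries is unlikely as the cause, since 85.4% of the 261 genes were still called after the length correction. The CoCl2 replicate 1 of each strain lay further from the untreated libraries than replicate 2, and 19 genes were called without rox1 CoCl2 replicate 2, so the number of calls rested on few libraries, and without rox1 replicate 2 the calls were 248 higher and 256 lower.

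Short genes made up 107 of the 198 genes called for rox2 against WT in CoCl2. If a trend of gene length between libraries was the cause, fewer than 50% of the genes should stay called after the length correction, and only 1% did. The correction removes any trend of length by construction, so this value shows only that few calls stood out beyond the trend, and what produced the trend stays open. The rank correlation across genes of a library's deviation with length was −0.294 in rox2 replicate 3 and 0.059 in rox2 replicates 1 and 2 without CoCl2, and −0.239 and −0.403 in the rox2 CoCl2 libraries. It was 0.167 and 0.249 in the WT CoCl2 libraries, so both sides of the comparison deviated and the trend did not rest on rox2 alone. Reads outside genes were 14.47% in rox2 replicate 3 and 19.88% and 10.13% in the rox2 CoCl2 libraries.

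NCAS0A11110, the neighbour of ROX1, was 11-fold higher in rox1/rox2 than in WT. A local effect of the altered ROX1 locus would likely give similar levels in rox1 and rox1/rox2, but the level in rox1/rox2 was 4.96-fold that in rox1 (adjusted p = 0.0353). That call was lost in 3 of 4 fits without a single library (up to 0.36), while the log2 fold change stayed between 1.99 and 2.60 in all alternatives, so the lost calls do not speak for a local effect. The log2 fold change of rox1/rox2 was 3.46 over WT and 2.31 over rox1. The fitted level in rox1 thus lay above WT, a difference that was not called in rox1 against WT. By the condition set, a local effect and an effect that needs the loss of both genes cannot be told apart.

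For hypoxia, 1 of 10 splits of the 6 libraries into 2 groups, the real one, gave 361 calls and the highest other split gave 0. For rox2 against WT, 1 of 10 splits, again the real one, gave 4 calls and the highest other gave 0. The splits used fits without a block, so those of hypoxia did not keep the replicate pairs. In both comparisons the splits are too few for a share under 0.05.

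The tests of whether a response differed between strains picked out the following results. For CoCl2 in rox1 against WT they were NCAS0D00350 (2.58), PXR1 (2.13), GPP2 (2.04), NCAS0B02500 (−5.64), HXK1 (−4.85) and EGO4 (−4.27), of which only NCAS0B02500 kept its call in every alternative. The level of NCAS0B02500 carried the doubt on shared reads. For rox2 there were 5 genes, with AVO2 (1.73), SBH1 (1.24), RFA3 (1.14) and MSS11 (−1.65) named. For rox1/rox2 there were 22, with RIM2 (1.43), SMB1 (1.20), NCAS0B02500 (−4.81), ISF1 (−3.99) and NCAS0H01880 (−3.98) named. Losing both genes differed from the sum for 22 genes, with CAR1 (3.17), CAR2 (2.58), AHA1 (2.17), ARG3 (−4.12), NCAS0A04610 (−3.60) and NCAS0C05370 (−3.54) named.

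Gene lists also passed these tests with the preset correlation. For CoCl2 in rox1 the median differences were −0.47 for ergosterol synthesis, −1.07 for the respiratory chain, −0.94 for the TCA cycle, −0.80 for gluconeogenesis, −0.33 for zinc and other metals, −1.16 for heat shock, 0.56 for cytosolic ribosomal proteins, 0.90 for ribosome biogenesis, −0.33 for phosphate supply and −1.27 for quiescence. For rox2 they were 0.23 for oxidative stress, 0.35 for cytosolic and 0.092 for mitochondrial ribosomal proteins, 0.24 for the proteasome and −0.39 for the cell cycle, in a comparison whose differences followed coding length (rank correlation −0.639 across genes). For rox1/rox2 they were −0.77 for ergosterol synthesis, −0.83 for the respiratory chain, −0.75 for the TCA cycle, −0.50 for heat shock, 0.22 for cytosolic ribosomal proteins, 0.38 for ribosome biogenesis, 0.13 for mitochondrial ribosomal proteins, 0.26 for the cell wall and −0.66 for quiescence. For the loss of both genes against the sum they were 0.68 for heat shock, −0.73 for cytosolic ribosomal proteins, −0.48 for ribosome biogenesis, 0.54 for the proteasome, −0.22 for amino acid synthesis, −0.48 for the cell wall and −0.30 for mating. None held with an estimated correlation.

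Reads outside genes made up a larger share than in any untreated WT library of the deletion experiment (5.19%) in 13 of its 18 libraries. They were 9.08% to 10.51% in the oxygen experiment, which was sequenced otherwise. The shares were 5.51% and 6.22% in rox1, 14.47% in rox2 replicate 3, 6.14% and 5.79% in rox1/rox2, 7.9% and 7.89% in WT with CoCl2, 6.54% and 6.03% in rox1 with CoCl2, 19.88% and 10.13% in rox2 with CoCl2, and 6.14% and 8.36% in rox1/rox2 with CoCl2. The choice to list every such library and every called list was made after the values had been seen.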

How the results depend on the processing

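The fits without rox1 replicate 1 and rox2 replicate 3, the length correction, robust estimation, the CoCl2 libraries alone with a block, the block with an estimated correlation, and hypoxic sets without a minimum fold were chosen after results had been seen. For counts that moved by more than 1.5-fold and are listed here, the cause was not tested.

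Leaving out 1 library gave 169 to 411 calls for hypoxia (361 with all), 2 to 291 for rox1 (3), 1 to 23 for rox2 (4), 3 to 4 for rox1/rox2 (6), 1470 to 2721 for CoCl2 in WT (2607), 126 to 930 in rox1 (447), 1493 to 2824 in rox2 (2667) and 40 to 390 in rox1/rox2 (321). For the differences in CoCl2 response it gave 19 to 504 for rox1 (261), 0 to 164 for rox2 (5) and 4 to 188 for rox1/rox2 (22). It gave 5 to 220 for both losses against the sum (22), 0 to 506 for rox1/rox2 against rox1 (18) and 15 to 153 against rox2 (124). Against WT in CoCl2 it gave 94 to 1347 for rox1 (974), 10 to 152 for rox2 (198) and 51 to 252 for rox1/rox2 (278). Where edgeR called 0 for rox2, 773 genes had an unadjusted p under 0.05 with all libraries and DESeq2 called 146. For rox1/rox2 against rox1, the 2 numbers were 1148 and 356.

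DESeq2 called more genes than edgeR in the deletion experiment: 45 for rox1, 65 for rox2, 166 for rox1/rox2, 730 for CoCl2 in rox1 and 679 in rox1/rox2. For the differences in CoCl2 response it called 639 for rox1, 146 for rox2 and 229 for rox1/rox2. It called 138 for both losses against the sum, 356 for rox1/rox2 against rox1, 366 against rox2, and 582 for rox2 and 475 for rox1/rox2 against WT in CoCl2.

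With only the compared groups in the fit, edgeR called 39 genes for rox1, 29 for rox2, 2796 for rox1/rox2, 52 for CoCl2 in rox1, 1631 in rox2 and 77 in rox1/rox2. The differences in CoCl2 response had 0 calls for rox2 and 134 for rox1/rox2. It called 319 for both losses against the sum, 262 for rox1/rox2 against rox1 and 580 against rox2. Against WT in CoCl2 it called 98 for rox1, 0 for rox2 (where the full fit had 1266 genes with an unadjusted p under 0.05) and 4 for rox1/rox2. This alternative estimates the spread from 4 or 5 libraries in most comparisons.

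With total counts the differences in CoCl2 response had 85 calls for rox1 and 0 for rox2, rox1/rox2 against rox2 had 391, and against WT in CoCl2 there were 103 for rox2 and 170 for rox1/rox2. With a minimum of 50 counts, rox2 had 1 call. The length correction left 1 call for rox2, 0 for the difference in CoCl2 response of rox2 and 3 for rox2 against WT in CoCl2. Over the genes called before it, the median absolute log2 fold change stayed at 1.7 for rox2, where CAR2 and ALD6 were at −1.36 and −1.08 (adjusted p = 0.0526 each), and went from 1.24 to 0.90 and from 0.97 to 0.41 in the others. Without rox1 replicate 1 and rox2 replicate 3 there were 17 calls for rox2, 177 for CoCl2 in rox1, 45 and 334 for the differences in CoCl2 response of rox1 and rox2, and 1 for rox1/rox2 against rox1.

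With the replicate number as a block, hypoxia lost no call of a named gene and, of lists, only iron uptake (0.0786), while ergosterol, oxidative stress and respiratory genes reached 0.0857 with a block and an estimated correlation together. Hypoxia had 741 calls with the block, rox2 8, the differences in CoCl2 response 435 for rox1 and 0 for rox2, and rox1/rox2 against rox1 had 31. In the deletion experiment, same-numbered libraries correlated at 0.254, 0.732 and 0.658 for rox1, rox2 and rox1/rox2 against WT in CoCl2. Each had 2 pairs, which is too few within 1 comparison to take the numbers as pairing. In every other comparison at least 1 pair was under 0.1, for example −0.305 for CoCl2 in rox2. In each strain, however, CoCl2 replicate 1 lay further from the untreated libraries than replicate 2. On the first principal component they lay at 53.5 and 30.8 in WT, 4.6 and −14.9 in rox1, 60.1 and 30.6 in rox2, and 42 and 17.1 in rox1/rox2. A replicate effect shared by the strains in CoCl2 therefore stays possible. Against WT in CoCl2, the block gave 1129, 232 and 258 calls, and the CoCl2 libraries alone with a block gave 1380 (554 higher, 826 lower), 294 (270 and 24) and 36 (3 and 33). In that last fit NCAS0A11110, NCAS0G01840 and NCAS0C00720 had adjusted p of 0.0638, 0.0752 and 0.0623.

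Of 2225 fits of named genes, 1915 kept the call and 310 lost it, and none turned direction. MSS11 kept its call in all 3 deletions (adjusted p up to 0.00602 in rox1, 0.0117 in rox2 and 0.00849 in rox1/rox2). In hypoxia 27 of 34 named genes and with CoCl2 in WT 34 of 36 kept their calls throughout, against 1 of 6 for the difference in CoCl2 response of rox1 and none of the 4 for rox2, the 5 for rox1/rox2 and the 6 for rox1/rox2 against rox1. Of tests of gene lists, 224 stayed and 82 were weaker. With an estimated correlation 4 stayed and 47 were weaker, and with fry 26 stayed and 25 were weaker. Of tests of hypoxic sets, 173 stayed, 17 were weaker, 15 were stronger and 3 turned direction. With a minimum of 4-fold in hypoxia, 8 stayed, 7 were weaker and 1 was stronger. The genes lower in hypoxia turned direction when no minimum fold was asked, with medians of 0.097 in rox1/rox2 against WT, 0.031 against rox1 and 0.037 against rox2 (adjusted p = 0.432, 0.56 and 0.401). The correlation across genes of the rox1 and rox1/rox2 effects moved from 0.264 to 0.14 with genes of log2 CPM 4 or more.

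The main limits were 2 libraries in 6 of the 8 groups of the deletion experiment and libraries that differed in reads outside genes. Depth limited the lowest levels, so ROX1 in the groups without a ROX1 count was only bounded. Power was limited too, since 65% of genes simulated with a 2-fold change and the pooled spread were recovered for rox1 against WT without CoCl2. That simulation had 164 calls against 3 in the data, so the share in the data was likely lower.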

Other observations

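Among further members of the fixed lists, CoCl2 in WT raised the acetate and glyoxylate genes CAT8 and ACS1 (log2 4.09 and 3.39) and the methionine genes MET2, MUP3 and MET17 (3.15, 3.26 and 1.94). It also raised the copper transporter gene CTR1 (2.06), which fell in hypoxia (−1.52), and the zinc transporter gene ZRC1 (1.57). The meiotic genes IME2, HOP2 and MND1 rose by 2.51, 3.19 and 3.02, while the cell wall genes CCW12 and CIS3 and the cyclin genes CLN1 and CLB6 fell by 2.09, 1.88, 1.28 and 1.62. The CoCl2 responses of CTR1 and ZRC1 were lower in rox1 than in WT (differences, rox1 minus WT, −2.78 and −2.75).

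Within hypoxia, the fatty acid synthase genes FAS1 and FAS2 rose by 0.44 and 0.38 log2 and SUR2 for sphingolipid synthesis by 0.59, while ELO1 and SCS7 fell by 0.64 and 0.40. The glycogen genes GLC3 and GSY1 rose by 0.66 and 0.43.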
